A study of Danio rerio with 4 samples.

How the data were processed

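Whole-embryo RNA of zebrafish at 6 somites was compared between 2 control and 2 tbx1 mutant libraries. Per the labels' protocols, tail tissue and some yolk were taken off each embryo for genotyping, polyadenylated RNA was made into libraries with a TruSeq kit, and these were sequenced in paired ends on an Illumina instrument. The submitters' processing notes name TopHat2 2.0.8, TopHat, Cufflinks 2.1.1, Cuffdiff 2.0.2 and the danRer7 (Zv9) build; which of these made the deposited values, and in which order, is not given in the sources used here. The authors deposited 1 table of FPKM values per gene and library, with 95% bounds, an estimate status, a Zv9 locus, an Ensembl gene ID and a symbol; its columns are titled RPKM per the file headers, and a stray header line at its end says FPKM. Read totals, counts, variants in the libraries and the Zv9 annotation were not used here.

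The table held 32538 genes. For 32400 the status was OK in all 4 libraries; the other 138 were left out, 20 of them with a mean of at least 1 FPKM. Among these are krt18 and mcm4, chosen after their values were seen. A further 18952 genes had a mean below 1 FPKM, which left 13448 genes to test. Values were used as deposited, as log2(FPKM + 0.5). This pseudocount draws the fold changes of low genes toward 0, so they are understated. Relative depth was read from the spacing of the lowest values in each library; whole reads could not be recovered, so the count models planned for that case were not run.

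Genes were tested with limma 3.58.1 in R 4.3.3 (a linear model of genotype, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries per group the moderated test had 4.66 degrees of freedom, 2.66 of them from the prior. Of 31 gene lists fixed before the data were examined (heart, pharynx, germ layers, signalling pathways, brain, stress, housekeeping and yolk genes), 30 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists. Of 638 list members, 590 were matched by the table's symbol, 21 by the current symbol of their gene ID, and 27 were not matched. For each chromosome the share of genes with an unadjusted p under 0.05 was compared with that of all other genes by Fisher's exact test, two-sided, and windows of 5, 10 and 25 Mb around tbx1 were compared with the other chromosomes, with tbx1 itself left out.

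The genes named in the text were set by a rule fixed before the data were examined: tbx1 and nkx2.5; up to 12 genes per direction, called ones first and then those of lowest p whose 2 mutant values did not overlap the 2 control values; the 4 tested members of lowest p from each list; and up to 6 genes within 10 Mb of tbx1. Other genes are said to have been chosen after their values were seen. Of the genes and lists set in this way, 1 list and a few genes are not reported here. Settings varied as laid down beforehand were pseudocounts of 0.1 and 1, no minimum or a mean of at least 5 FPKM, quantile normalization, median-ratio rescaling, the replicate number as a block, leaving out each library, no trend, robust empirical Bayes and a threshold of 0.10. Settings added after seeing the data were leaving out loci under 300 bp, without and with the block, leaving out chromosome 5, and the ribosomal list without the S6 kinase genes. The fit was tested on simulated data with changes of known size; figures were drawn with matplotlib 3.10.9.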

Results

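RNA was measured in zebrafish embryos at 6 somites, 12 h after fertilization, from wild-type controls and from tbx1 mutants carrying the vgo (van gogh) allele, which the labels call null. tbx1 encodes a T-box transcription factor, and its human counterpart lies in the chromosome region that is deleted in DiGeorge syndrome. Each group had 2 libraries of polyadenylated RNA, made from the embryo that was left after tail tissue and some yolk had been taken off for genotyping. The deposited table gave FPKM values for 32538 genes, of which 13448 had a mean of at least 1 FPKM and a usable estimate in all 4 libraries. Read totals were not given, but the spacing of the low values put the depth of control 2, mutant 1 and mutant 2 at 0.840, 0.822 and 0.725 of that of control 1. The width of the authors' 95% interval, divided by 2 and taken relative to the value, had a median of 8.25% in control 1 and 9.54% in mutant 2. Across genes with loci of at least 300 bp, log2 values correlated at 0.993 between the controls and 0.992 between the mutants, against 0.995 between control 1 and mutant 1 and 0.995 between control 2 and mutant 2. Genes are not independent replicates. The labels do not say whether the controls were siblings of the mutants or whether a library was a pool, so p-values measure only the spread between these samples, which may be technical.

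The first comparison asked how far RNA of tbx1 itself, and of nkx2.5 from the series title, differed between the genotypes. tbx1 RNA (ENSDARG00000031891, Zv9 chromosome 5 from 16906409 to 16919398) was present at 9.08 and 9.14 FPKM in the controls and at 4.91 and 4.52 FPKM in the mutants. The group means were 9.11 ± 0.0417 and 4.71 ± 0.276 FPKM (SD, n = 2 each), a ratio of 0.517. On the log2(FPKM + 0.5) scale the difference was -0.88 (SE 0.0910, 95% interval -1.12 to -0.64). Before adjustment, the limma p of tbx1, a gene named beforehand, was 2.87e-04. Adjusted by Benjamini-Hochberg over all genes tested, it was 0.227, which missed the threshold. Among the alternatives run, tbx1 passed only with the replicate number as a block and loci under 300 bp left out, a setting chosen after seeing the data. The authors' 95% intervals for tbx1 ran from 8.43 to 9.86 FPKM over the controls and from 4.02 to 5.41 FPKM over the mutants, without overlap. Of all values tested, however, 26.0% lay outside their own deposited interval, so neither overlap of these bounds nor its absence is firm evidence. nkx2.5 (ENSDARG00000018004, chromosome 14 from 25240904 to 25243698), a homeobox gene of heart progenitors, was close to the lower limit of testing at this stage. Its values were 1.69 and 1.35 FPKM in the controls and 0.526 and 1.17 FPKM in the mutants, a ratio of 0.556 of the means. Its log2 difference of -0.62 (SE 0.286, 95% interval -1.38 to 0.13) had an unadjusted p of 0.0850 and an adjusted p of 1.0 in limma. The authors' intervals of control 2 (0.818 to 1.43 FPKM) and mutant 2 (0.678 to 1.28 FPKM) overlapped. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so these single-gene calls rest on limma's pooled spread.

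**Figure D1:**
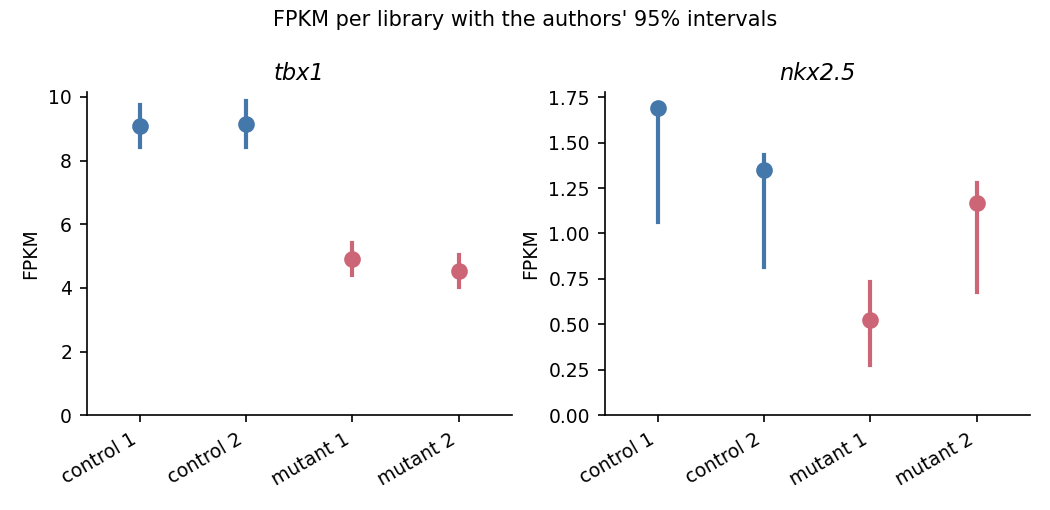
FPKM of tbx1 (left) and nkx2.5 (right) in each library, controls in blue and mutants in red; points are the deposited values and vertical lines the authors' 95% intervals. The tbx1 values of 9.08 and 9.14 FPKM in the controls stand above those of 4.91 and 4.52 FPKM in the mutants, while the nkx2.5 intervals of control 2 and mutant 2 overlap.

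Mutants and controls were next compared gene by gene, as the series' design states. Very short loci, most of them genes of small noncoding RNAs, made up all 9 genes that passed an adjusted p of 0.05 in limma, 5 of them lower and 4 higher in the mutants. The muscle microRNA gene dre-mir-133b was listed at 1177 and 1222 FPKM in the controls and at 0 in both mutants. The C/D box small nucleolar RNA SNORD24 on chromosome 5 was listed at 734 and 999 FPKM in the controls and SNORD65 at 528 and 702 FPKM, each with 0 in both mutants. Also listed at 0 in both mutants were CABZ01078244.3 (379 and 524 FPKM in the controls) and CR933818.1 (87.8 and 64.0 FPKM). In the other direction, AC024175.24 on the mitochondrial chromosome was listed at 0 in both controls and at 1898 and 1126 FPKM in the mutants. The corresponding mutant values were 19.9 and 28.4 FPKM for a 5S_rRNA copy on chromosome 17, a mean of 12.9 FPKM for 1 locus of SNORA65 and 4.18 and 5.84 FPKM for SNORA29, all listed at 0 in both controls. The next SNORA65 locus on chromosome 5, chosen after its values were seen, stood at 101 FPKM in the controls and 64.1 FPKM in the mutants. All 9 loci are shorter than 300 bp. Of the values at such loci 57.2% lay outside their own deposited interval, against 25.4% at longer loci, and a 0 at such a locus need not mean that the RNA was absent, so no fold was formed. With 1 library left out the count went to 30 (without control 1), 28 (control 2), 39 (mutant 1) or 37 (mutant 2), nearly all of them short loci.

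Outside the short loci the lowest p-values belonged to genes that missed the threshold over all genes. anxa1a, which encodes a phospholipid-binding annexin, stood at 228 ± 11.6 FPKM in the controls and 92.1 ± 7.52 FPKM in the mutants (SD, n = 2 each), a log2 difference of -1.31 (SE 0.0876, adjusted p = 0.0551 in limma). bcdo2l, a gene of the carotenoid-cleaving oxygenase family, went from 15.3 to 6.14 FPKM (log2 -1.25, adjusted p = 0.0588 in limma), and thy1, a surface glycoprotein gene, from 21.2 to 9.94 FPKM (log2 -1.05, adjusted p = 0.0590 in limma). tagln2, encoding an actin-binding transgelin, went from 344 to 194 FPKM (log2 -0.82), and ddr2l, encoding a collagen receptor kinase, from 9.01 to 2.98 FPKM (log2 -1.46), both with an adjusted p of 0.0884 in limma. These 5 genes lie on chromosome 5, as tbx1 does, while si:dkey-148f24.3 on chromosome 23 went from 2.62 to 0.395 FPKM (adjusted p = 0.132 in limma). On the higher side, si:dkey-68l7.1 on chromosome 23 stood at 0.904 FPKM in the controls and 4.34 FPKM in the mutants (log2 1.78, adjusted p = 0.152 in limma). olig3, a helix-loop-helix factor gene of the dorsal neural tube, had 0.0686 and 0.259 FPKM in the controls and 2.19 and 2.65 FPKM in the mutants (log2 2.15, adjusted p = 0.241 in limma), at a locus of only 372 bp. Other values that missed the threshold were a log2 difference of 1.42 for zgc:63972, 0.98 for crp4, 1.38 for zgc:165555, 0.74 for the linker histone gene histh1l and 0.81 for the secreted-protein gene cthrc1a. SNORA62, itself a short locus of 143 bp, was listed at 0 in both controls and at 7.12 and 24.6 FPKM in the mutants. When loci under 300 bp were left out, a setting chosen after seeing the data, anxa1a, bcdo2l, thy1, tagln2 and ddr2l fell (adjusted p = 0.0397 each in limma), si:dkey-148f24.3 fell (0.0452) and si:dkey-68l7.1 rose (0.0475). Of the 4 deposited values per gene, 4 lay inside their own interval for anxa1a and ddr2l. For si:dkey-148f24.3, at a locus of only 318 bp, 2 did. For thy1 the number was 1, and for bcdo2l, tagln2 and si:dkey-68l7.1 it was 0. These 7 calls shared 0 genes with the 9 above. All 7 also passed with robust empirical Bayes, a setting laid down beforehand. Among the other such settings, anxa1a and bcdo2l passed at a pseudocount of 0.1 and, with thy1, at a mean of at least 5 FPKM. anxa1a also passed after quantile normalization and with the replicate number as a block, and si:dkey-148f24.3 without trend.

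Most of the transcriptome differed little between the genotypes. Of the genes tested, 94.3% had a log2 difference within 0.3, and 267 had an unadjusted limma p under 0.05 (145 higher, 122 lower), against 672.4 by chance alone. The 2 mutant values lay entirely above or below the 2 control values for 24.8% of genes, where chance gives 33.3%. Split by library number instead (control 1 and mutant 1 against control 2 and mutant 2), 2605 genes had an unadjusted limma p under 0.05. The genotype fit had no block, so this difference entered its residual spread and can lower both the count of 267 and the share of 24.8%. Their shortfall against chance is therefore no evidence that the genotypes do not differ. In simulated data of the same size, 27.7% of genes changed by 1.5-fold, 73.2% of those changed by 2-fold and 98.4% of those changed by 4-fold were called, with 11 false calls among 144. With 144 calls the adjusted threshold was easier to pass than with the 9 of the real data. Because the threshold was easier to pass, the simulated shares are likely too high for the real data. The simulated noise was also independent between libraries, without a difference by library number. How this changes the shares was not tested.

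Gene lists for the tissues and pathways of the embryo, fixed before the data were examined, asked whether groups of genes differed together. None of the 507 list members tested passed over all genes in limma; 10 had an unadjusted p under 0.05, and 96.6% lay within 0.3 on the log2 scale. Among the 12 tested members of the cardiac progenitor list, most of them transcription factors (median -0.022), nkx2.7 had a log2 difference of -0.14, tmem88a of 0.19 and mef2cb, on chromosome 5, of 0.56. The means of hand2 and gata5, chosen after their values were seen, lay close together: hand2 was at 26.8 FPKM in the controls and 26.2 FPKM in the mutants and gata5 at 61.4 and 60.9 FPKM. Only actc1a of the heart muscle list reached 1 FPKM (65.6 in controls, 61.2 in mutants), so that list was not tested. Of the 9 pharyngeal mesoderm genes (median 0.081), lhx2b had a log2 difference of 0.30 and foxf2a of -0.15. The median of the cardiac progenitor list was below 0 although its mean was 0.016. The 33 genes studied with tbx1 elsewhere had a median of -0.019, with fgf3 at -0.21 and the retinoic acid-degrading cyp26c1 at -0.22. Adjusted over the list alone, the numbers of members passing in these lists were again 0.

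Endoderm and neural crest genes leaned in opposite directions without reaching the threshold at the settings used throughout. Of 14 endoderm and pharyngeal pouch genes, 11 were lower in the mutants (median -0.068), among them foxa1 (-0.14), pax9 (-0.21) and the redox gene prdx5 (-0.07), with an adjusted p of 0.0927 in limma's camera test. Of 17 cranial neural crest genes, 14 were higher (median 0.071), with zic2a at 0.15, twist1a at 0.14 and tfap2c at 0.14, and the same adjusted p of 0.0927 in camera. Of 15 yolk syncytial layer genes, 12 were lower (median -0.083), including the lipoprotein genes apoa1a (-0.19) and apoeb (-0.12) and the protease inhibitor genes serpina1 (-0.08) and serpina1l (-0.09), at an adjusted p of 0.0927 in camera. Some yolk had been taken off each embryo, and how much was left in each library is not given in the sources used here. This lean can therefore not be told apart from the dissection. With an estimated correlation, the adjusted p of all 3 lists was 0.955, and after quantile normalization the yolk syncytial median was -0.008. With the replicate number as a block, a setting laid down beforehand, all 3 lists passed in camera, though no label gives the number a meaning. In camera the endoderm list passed with no minimum, the neural crest and yolk syncytial lists passed at a mean of at least 5 FPKM, and the neural crest list passed without mutant 2.

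Cytosolic ribosomal protein genes were the only list past the threshold in camera, by a very small amount: 61 of 78 members were lower in the mutants (median -0.039, adjusted p = 0.00808 in limma), but the median was 0.003 after quantile normalization. The call was lost with an estimated correlation (adjusted p = 0.955 with an estimated correlation), in limma's fry (adjusted p = 0.989), after quantile normalization, with no minimum, and without control 1, control 2 or mutant 2. Without these libraries in turn camera called 1, 0 and 7 lists, and 2 without mutant 1. The members of lowest p were rpl12 (-0.19), rps7 (-0.13), rps6ka3a (0.09) and rpl11 (-0.12). The list's pattern also took in S6 kinase genes, which are not ribosomal proteins, and 4 of these were tested, rps6ka3a among them; without them, 60 of 74 were lower. Their mean log2 level was 11.20 in mutant 2, against 11.30, 11.29 and 11.31 in control 1, control 2 and mutant 1, so mutant 2 alone sat low. The 13 mitochondrially encoded genes had a median of -0.010 and a mean of 0.001, with mt-nd6 at 0.09, mt-nd5 at 0.06, mt-cyb at -0.05 and mt-nd2 at -0.03.

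Surface, muscle and axial groups did not pass as lists at the settings used throughout, though single members stood apart. The tailbud list passed in camera with the replicate number as a block. When 1 or another library was left out, the sign turned for unc45b, smyhc1, col2a1a, ntn1a, col8a1a, hoxb10a, wnt8a, sp5l and ntla, and in other lists for actc1a, nog1, lft1, coe2, mt-cyb and mt-nd2. anxa1a was the only member of any list to pass when adjusted over the list alone (adjusted p = 6.96e-04 in limma among the 17 enveloping layer and periderm genes). The list median was 0.009 and the mean -0.041, with cldnf at 0.18, agr2 at 0.26 and icn at 0.14. The 13 skeletal muscle genes had a median of -0.054 and a mean of 0.053. Among them the creatine kinase gene ckma on chromosome 5 was at 1.02 FPKM in the controls and 2.34 FPKM in the mutants (log2 0.92), while unc45b was at -0.14, myog at 0.19 and smyhc1 at 0.24. The 12 notochord and floor plate genes had a median of 0.010, with col9a2 at 0.26, col2a1a at 0.11, ntn1a at 0.09 and col8a1a at 0.06. The 18 presomitic mesoderm and segmentation genes had a median of -0.032, with foxc1b at -0.25, foxc1a at -0.18, her12 at -0.16 and dld at 0.09. Of 10 tailbud genes, 9 were lower in the mutants (median -0.088), with hoxb10a at -0.23, wnt8a at -0.15 and sp5l at -0.07. Some of the list's genes also differed with the library number, as ntla did, at 15.0 and 21.3 FPKM in controls 1 and 2 and at 12.9 and 19.1 FPKM in mutants 1 and 2.

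Among the signalling lists, the Notch list of 22 genes (median 0.023, mean -0.006) held 3 members with an unadjusted limma p under 0.05, and the FGF, BMP, Wnt and retinoic acid lists held 0. The 3 were hey2 (4.45 to 3.03 FPKM, log2 -0.48), notch1a at a 249 bp locus (0.28) and nrarpb on chromosome 5 (0.24), with her4.1 next at -0.39. The FGF list of 17 genes had a median of 0.019, with fgf17 at 0.23, fgf10b at 0.23 and il17rd at -0.14. The retinoic acid list of 19 genes had a median of -0.035, with rdh10b at -0.11, hoxb5b at -0.13 and rarga at -0.15. The 23 BMP genes had a median of 0.071, with szl at 0.45, nog1 at 0.18, msxc at 0.19 and id3 at 0.07. The 22 Wnt genes had a median of 0.023, with wnt8b at 0.20, axin2 at 0.16, nkd1 at 0.13 and wnt1 at 0.25. The 9 left-right and motile cilia genes had a median of 0.059, with ccdc103 at -0.34, rfx4 at 0.14 and lft1 at 0.12.

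Brain, placode and blood lists did not pass in camera at the settings used throughout (lowest adjusted p = 0.254 in limma). Of 21 forebrain and eye genes, 19 were higher (median 0.059), with pax6b at 0.19 and fezf2 at 0.21, but hesx1 was at 60.1 FPKM in the controls and 48.5 FPKM in the mutants (log2 -0.31). The 20 midbrain and hindbrain genes had a median of 0.051, with gbx1 at 0.25, eng2a at 0.12 and hoxd4a at -0.22. The 18 neuronal genes had a median of 0.019, with tubb5 at 0.09, gap43 at 0.19, coe2 at 0.13 and onecut1 at -0.12. The 14 otic and preplacodal genes had a median of 0.014, with six4b at 0.15, eya4 at 0.30, irx7 at 0.11 and atoh1b at -0.14. The 13 blood and endothelial genes had a median of 0.099, with spi1 at 0.34, egfl7 at 0.30, klf4 at 0.08 and cebpa at -0.09.

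The cell cycle, stress, hypoxia, maternal and fading lists did not pass in camera at the settings used throughout (lowest adjusted p = 0.217 in limma). The 25 cell cycle genes had a median of -0.002, with cdca8 at -0.10, ccnb2 at -0.10, ccnd1 at 0.08 and tyms at 0.08. The heat shock and immediate early list of 19 genes had a median of -0.028 and a mean of 0.044, with hsp90aa1.2 at -0.28, dnajb1b at -0.15, gadd45ba at -0.13 and klf2a at -0.13. The 16 hypoxia and glycolysis genes had a median of 0.037, with pfkfb3 at 0.39, aldocb at 0.23, ankrd37 at -0.16 and pfkfb4 at -0.09. Of the 10 maternal and germ line genes (median -0.009, mean -0.13), the TGF-beta family gene dvr1 was at 15.2 FPKM in the controls and 9.65 FPKM in the mutants (log2 -0.65). Others were ca15b at -0.44, nanos3 at -0.28 and oep at 0.10. The 17 genes fading after gastrulation had a median of -0.003, with nanog at -0.28, vox at -0.12, aplnrb at -0.10 and foxh1 at 0.09. Notochord, neuronal, cell cycle and mitochondrial medians changed sign under quantile normalization.

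**Figure D2:**
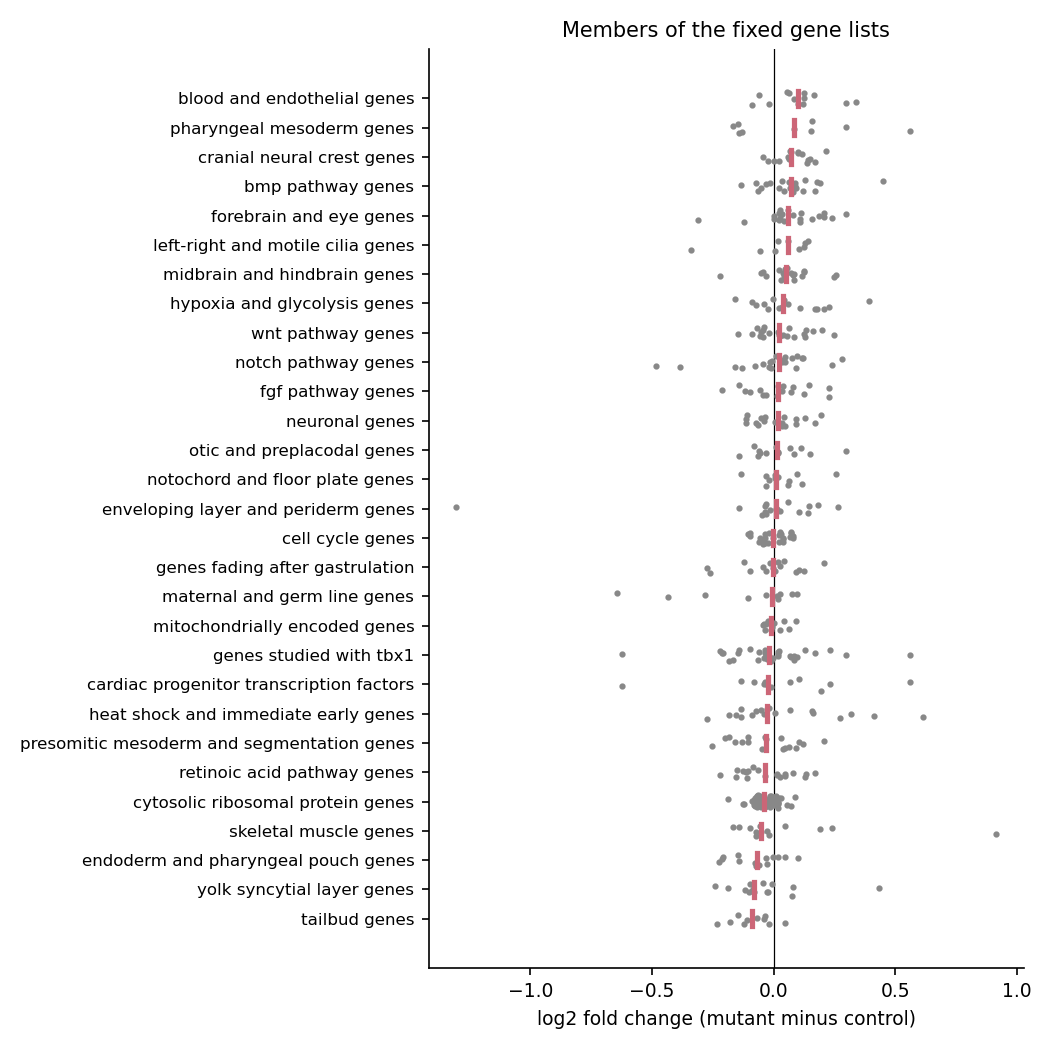
Log2 fold change (mutant minus control, on the log2(FPKM + 0.5) scale) of each tested member of the gene lists described in the text, 1 grey point per gene, with the list median as a red bar. The medians lie between -0.09 (tailbud) and 0.10 (blood and endothelial), and the point farthest from 0 is anxa1a at -1.31.

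The last comparison asked where in the genome the differing genes lie. Chromosome 5, which carries tbx1, held 65 of its 779 tested genes with an unadjusted limma p under 0.05, or 8.34%, the highest share of the 25 chromosomes. Of all other genes, 1.59% had such a p, which gives an odds ratio of 5.62 (95% interval 4.14 to 7.55, Fisher's exact test, two-sided, p = 6.46e-24, adjusted over the chromosomes 1.61e-22). Fisher's exact test, here and for the windows below, takes genes as independent. Genes measured in the same libraries are not, so its p does not measure variation between embryos. The chromosome 5 genes went both ways, 39 lower and 26 higher in the mutants. Beyond the genes above they included, chosen after their values were seen, the lysosomal enzyme gene hexb (43.8 to 30.5 FPKM), dpp7 (159 to 112 FPKM) and efha1 (9.89 to 5.15 FPKM) on the lower side, and prkaa1, an AMP-activated kinase subunit gene (10.4 to 14.1 FPKM), and prdx4 (29.0 to 37.4 FPKM) on the higher side. The median log2 difference of all chromosome 5 genes was 0.01, against 0.02 elsewhere. Changes at least as large as that of tbx1, at loci of 300 bp or more, were found in 15 of 762 genes on chromosome 5 (1.97%) and in 18 of 12186 on the other chromosomes (0.148%, Fisher's exact test p = 1.18e-10).

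The low p-values on chromosome 5 were found both near tbx1 and far from it. Within 5 Mb of it, 2 of 79 genes had a p under 0.05 in limma (odds ratio 1.69 against other chromosomes, 95% interval 0.200 to 6.42, Fisher's exact test p = 0.337). Within 10 Mb there were 10 of 197 (5.08%, odds ratio 3.49 against other chromosomes, 95% interval 1.62 to 6.70, Fisher's exact test p = 0.00108). Those within 10 Mb included ddr2l, the sugar transporter gene slc2a11b (4.67 to 1.47 FPKM, log2 -1.39), zgc:158343 (-1.06), zgc:66350 (-0.86) and the mitochondrial ribosomal gene mrpl41 (33.7 to 22.2 FPKM, log2 -0.59), and C5H5orf34 at 0.78. Between 30 and 40 Mb, 20 of 142 genes (14.1%) had such a p, as did 9 of 67 (13.4%) between 50 and 60 Mb. Within 25 Mb of tbx1 the share was 8.58% and farther away on the chromosome 7.69%, an odds ratio of 1.13 between these parts (95% interval 0.647 to 2.0, Fisher's exact test p = 0.692).

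**Figure D3:**
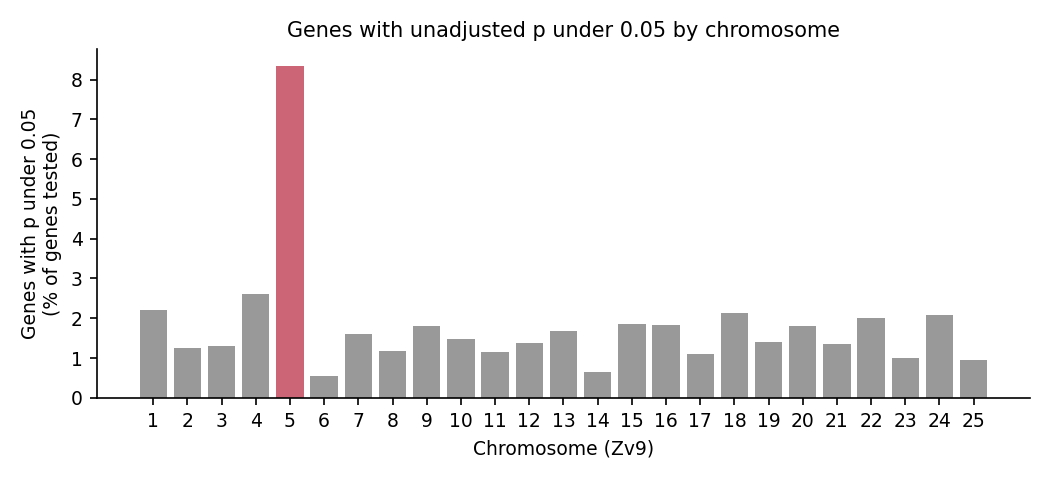
Share of tested genes with an unadjusted limma p under 0.05 on each of the 25 chromosomes of Zv9, in percent, with chromosome 5 in red. Chromosome 5 stands at 8.34%, and the next highest, chromosome 4, at 2.60%.

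**Figure D4:**
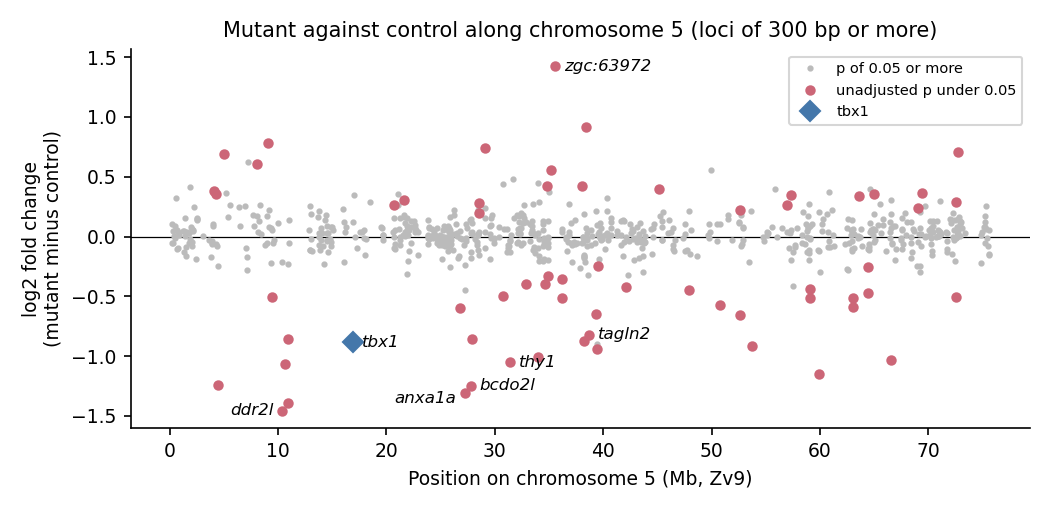
Log2 fold change (mutant minus control) of each tested gene with a locus of 300 bp or more along chromosome 5, by start position in Mb on Zv9; red points have an unadjusted limma p under 0.05, grey points do not, and the blue diamond is tbx1. The 63 genes with such a p, tbx1 among them, spread over the whole chromosome, with 38 lower and 25 higher in the mutants.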

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

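The count of 9 called genes lay between 7 and 10 under the other pseudocounts, minima and scalings, without trend and without chromosome 5. It was 16 with robust empirical Bayes and 14 at an adjusted p under 0.10. Without loci under 300 bp it was 7, but these 7 shared 0 genes with the 9, all of which were short loci. Leaving out 1 library gave 28 to 39 calls (30 without control 1, 28 without control 2, 39 without mutant 1, 37 without mutant 2); the group of 1 is then assumed to vary like the other group. Of these calls 30, 27, 37 and 37 were short loci. The count of lists, 1 by camera, was 0 with an estimated correlation, 0 with fry, 0 after quantile normalization, 3 at a mean of at least 5 FPKM (ribosomal, neural crest and yolk syncytial) and 4 at an adjusted p under 0.10, and 0 to 7 with a library left out (1 without control 1, the tailbud list; 0 without control 2; 2 without mutant 1; 7 without mutant 2). With no minimum the 1 list was the endoderm list instead of the ribosomal one. The odds ratio of chromosome 5 stayed above 1 with p under 0.05 in all alternatives run (log2 1.51 to 2.51, against 2.49). Called genes on chromosome 5, 2 at first, numbered 4 at a pseudocount of 0.1, 4 at a mean of at least 5 FPKM, 7 with robust empirical Bayes, 7 at an adjusted p under 0.10, 5 without loci under 300 bp and 1 to 4 with a library left out (1 without control 1, 4 without mutant 2). tbx1 and nkx2.5 kept their direction throughout, and nkx2.5 never passed. The cause of these shifts was not tested. The alternatives without short loci, without chromosome 5 and without the S6 kinase genes were added after seeing the data; the planned count model alternative was not run because the table holds no counts.

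Only 2 pairs share a replicate number and no label gives it a meaning. Deviations of same-numbered libraries correlated at -0.0051 over all loci and 0.347 over loci of 300 bp or more. With the replicate number as a block (replicate block), 9 genes and 5 lists were called, the endoderm, neural crest, tailbud, yolk syncytial and ribosomal lists. With loci under 300 bp left out as well, chosen after seeing the data, 24 genes were called, 16 of them on chromosome 5, and 5 lists; tbx1 then passed (log2 -0.88, adjusted p = 0.00976 in limma, against 0.128 to 1.0 in its other alternatives).

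Of 2282 single-gene values under the alternatives, 2202 gave the same call and direction, 12 lost the call and 45 gained it. The other 23, in 15 genes that had not been called, changed sign when a library was left out. The lowest and highest log2 values with a library left out were as follows. In muscle and axial genes these were actc1a (-0.29, 0.11), unc45b (-0.31, 0.0234), smyhc1 (-0.0809, 0.56), col2a1a (-0.0544, 0.28), ntn1a (-0.0670, 0.26) and col8a1a (-0.0436, 0.16). In tailbud genes they were hoxb10a (-0.56, 0.0872), ntla (-0.45, 0.0909), wnt8a (-0.40, 0.11) and sp5l (-0.18, 0.0505), and in others nog1 (-0.00586, 0.36), lft1 (-0.15, 0.39), coe2 (-0.00460, 0.26), mt-cyb (-0.10, 0.00514) and mt-nd2 (-0.15, 0.0807).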

Other observations

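Of the tests below, those of whether chromosome 5 varies between any libraries and of unstable short RNAs were planned before their results were seen; all other tests, and the gene lists of the next paragraph, were chosen after values had been seen.

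Relatives of tbx1 and counterparts of the genes deleted with human TBX1 were looked up as 2 lists. Of 9 other T-box genes tested, 0 passed in limma even when adjusted over the list alone, 0 had an unadjusted p under 0.05, and the median absolute log2 difference was 0.10; tbx6, a presomitic mesoderm gene, was at -0.10, ntla at -0.18, tbx2b at 0.16 and tbx16 at 0.21. The 23 tested zebrafish counterparts of genes in the human deletion region had a median absolute log2 difference of 0.0657, with ranbp1 at -0.07, crkl at 0.06, hira at 0.02 and gnb1l, the gene beside tbx1, at 0.12; 2 members that do not belong to the region were taken off this list after values had been seen. The exception was arvcfb, a cell-junction catenin gene on chromosome 5, at 5.03 ± 0.619 FPKM in the controls and 2.61 ± 0.855 FPKM in the mutants (log2 -0.86, adjusted p = 0.327 over the list alone in limma), the 1 member with an unadjusted p under 0.05.

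Libraries numbered 1 and 2 differed in both genotypes by many more genes than the genotypes did. In a limma fit of number and genotype over 13202 loci of 300 bp or more, 613 genes passed an adjusted p of 0.05, 324 higher and 289 lower in the libraries numbered 2. For genotype, the same fit called 24 genes. Higher were genes of the tailbud and presomitic mesoderm: msgn1 at 21.6 and 47.9 FPKM in controls 1 and 2 and 19.8 and 39.1 FPKM in mutants 1 and 2 (log2 1.05, SE 0.0663, adjusted p = 0.00183 in limma), the clock gene her7 (0.84), tbx6 (0.48), ntla (0.52) and the caudal gene cdx4 (0.51). Lower were the slow myosin gene smyhc1 (-0.57), the hatching enzyme gene he1a (-0.36), the endothelin receptor gene ednrab (-1.18) and sparc (-0.52). Of the lists, camera called 9. Among them were the tailbud list, with 5 of 10 members passing singly as higher, and the presomitic list, with 7 of 18. The BMP list was called as well (median -0.26, adjusted p = 3.39e-06 in camera). The others were the mitochondrial list (0.12) and, lower in the libraries numbered 2, the blood and endothelial (-0.25), enveloping layer (-0.16), neural crest (-0.13), Notch (-0.13) and ribosomal (-0.06) lists. Camera called 0 with an estimated correlation (lowest adjusted p = 0.716 in limma).

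Genes with p under 0.05 gather on chromosome 5, which carries tbx1. In the other splits of the 4 libraries the highest odds ratio for chromosome 5 was 0.956, against 5.62 (95% interval 4.14 to 7.55) for the real split. Each side of those splits holds 1 control and 1 mutant, so genotype differences on chromosome 5 enter their residual spread and can lower the odds ratio. The splits therefore cannot decide whether chromosome 5 varies more between any libraries. Besides, 3 splits are too few for a share under 0.05. Since 40% of the chromosome 5 genes with such a p were higher in mutants (exact 95% interval 28.0 to 52.9), poorer mapping that only lowers mutant values cannot be all of it. A stretch of chromosome inherited with the mutation may contribute, as a hypothesis, but an odds ratio of 1.13 (0.647 to 2.0, Fisher's exact p = 0.692) between genes within 25 Mb of tbx1 and the rest of the chromosome leaves its extent open. Mapping that raises some genes and lowers others, chromosome-wide parental differences and regulation within the chromosome were not tested.

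All 9 calls over all loci come from loci under 300 bp. Unstable values of short RNAs may be the source: the split of control 1 and mutant 2 against control 2 and mutant 1 held 19 short loci that were at 0 on 1 side only, the split by library number 9, and the real split 11. These splits called 13, 7 and 9 genes in turn, and 3 splits are too few for a share under 0.05. A loss of these RNAs in the mutants cannot be excluded for a single locus such as dre-mir-133b.

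The difference between libraries numbered 1 and 2 may have come with sampling of the embryos. Different amounts of tail tissue remain open. The tailbud list median was 0.39 (95% bootstrap interval 0.17 to 0.54) and the forebrain and eye list at -0.07 (-0.27 to 0.03). Of 21 forebrain and eye genes, 4 passed singly as lower and 0 as higher in the libraries numbered 2. Tailbud genes are where the difference was noticed, so these values do not test the amount of tail tissue. A different stage remains open as well: the skeletal muscle list was at -0.22 (-0.31 to 0.11) and the list of genes fading after gastrulation at 0.02 (-0.02 to 0.36), both with intervals that include 0. The split by number had 2605 genes with an unadjusted p under 0.05, against 267 for genotype, which points to a structure of the samples. Day, clutch and parents of the embryos are not given in the sources used here.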
